A study of Homo sapiens with 22 samples.

How the data were processed

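RNA was extracted with Trizol and libraries were made with a NEBNext Ultra RNA kit, per the labels' protocols. The authors aligned reads to the human genome build hg19 with HISAT2 2.1.0, per the submitters' processing notes. The deposited table holds 1 count per gene and library, and these counts were used here without realignment. The program that counted the reads, its annotation, the strand setting, any filters and the doses of the compounds are not given in the sources used here. Reads of a gene and of a transcript on the other strand at the same place can therefore not be told apart.

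The table held 20167 gene identifiers. Of these, 19299 had a symbol in the gene name table, 61 more had one only in GENCODE v29, and 807 had none. GENCODE v29 served for names alone, because its coordinates belong to another genome build. No library counted 1245 of the identifiers. Total counts per library lay between 6001519 and 22046301.

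Each experiment was fitted apart with edgeR 4.0.16 in R 4.3.3, because each had its own DMSO libraries. The fit used scaling factors by the trimmed mean of M-values (TMM) and 1 coefficient per group. The filterByExpr function kept genes with sufficient counts (minimum count 10, minimum total 15): 13578 genes in the factorial and 13718 in the time course. Comparisons were tested with the robust quasi-likelihood F-test, two-sided, with Benjamini-Hochberg adjustment over all tested genes of the comparison and a threshold of 0.05. Every adjusted p of a gene comes from this test. Standard errors (SE) of log2 fold changes were the absolute change divided by the square root of F. Levels (CPM) are counts scaled to a common library total with the TMM factors, as mean ± standard deviation (SD) over libraries.

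In the factorial, KDOBA67 was compared with DMSO, ISRIB plus KDOBA67 with ISRIB, ISRIB plus KDOBA67 with KDOBA67, and ISRIB with DMSO. The interaction tested whether the KDOBA67 response differed with ISRIB. In the time course, each time of KDOBA67 was compared with DMSO at 0 h and with the time before it. The 48 h responses of the experiments were compared by Pearson correlation over genes tested in both.

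The labels carry a replicate number and a donor number although all libraries came from 1 cell line. Nothing in the labels says that the libraries of a group were separate cultures. The p-values therefore measure only the spread between these libraries. Before the calls of any comparison were compared, the numbers were tested as a pairing by correlating each library's deviation from its group mean. Libraries of the time course with the same number correlated at 0.345 to 0.796 (20 pairs, median 0.49). With 2 libraries per group the other pairs mirror these, at -0.796 to -0.345. In the factorial, same-number libraries correlated at -0.0302 to 0.133 (18 pairs, median 0.018), against -0.115 to 0.0871 for the other 36 pairs. The replicate number was fitted as a block as an alternative in both experiments. Blocked values are given where they end or add a call or move a count by more than 1.5 times. The median biological coefficient of variation over genes was 0.04 in the factorial and 0.212 in the time course, and 0.0371 and 0.126 with the block. All 12 factorial titles carry r1, while the time course has r1 and r3, so the replicate numbers may not mean the same in both. Between libraries of a group, chi-square per degree of freedom (near 1 with counting noise alone) was 1.3 to 5.87 in the factorial and 30.3 to 113 in the time course. The factorial libraries thus also differed beyond counting noise, but far less than those of the time course. Among the factorial DMSO libraries, replicate 3 stood apart from replicates 1 and 2 (4.54 and 4.14, against 1.36 between replicates 1 and 2). Pairs of other factorial groups reached 5.87. Residual degrees of freedom were 8 and 5, and 6 and 4 with the block.

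The same code was tested on simulated data with 200 changed genes. In a comparison of 3 against 3 libraries with the factorial's spread, 86.6% of changes of 1.5-fold, 88.1% of 2-fold and 98.5% of 4-fold were recovered, with 6 false calls. In a comparison of 2 against 2 with the time course's spread, 0% of 1.5-fold, 1.49% of 2-fold and 60.6% of 4-fold changes were recovered, with 0 false calls. With the block these were 34.3%, 80.6% and 100%, with 7 false calls. None of 25 random gene lists was called. The simulation drew genes independently, so it could not test the preset correlation between list members. Its replicates also shared the same treatment effect, so the blocked recovery does not describe replicates that respond differently. Only 200 genes changed in it, in both directions, while KDOBA67 against DMSO called 10147 of 13578 genes. It therefore did not test the scaling or the false calls where most genes change.

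Named genes followed a rule. For KDOBA67 against DMSO, the ISRIB comparisons and 48 h of the time course, it took the 10 genes with the largest rise and the 10 with the largest fall. For the others it took 5 each. A gene had to pass the threshold, have a mean CPM of at least 5 and show no overlap between the libraries of the groups, which chance gives for 10% of genes with 3 against 3 libraries. A panel of TBXT, KDM6A, KDM6B, ATF3, ATF4, DDIT3, TRIB3, ASNS and CHAC1 belonged to every comparison. Up to 4 members with the smallest p were taken from each gene list. In the time course the rule was also applied to the blocked fit.

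There were 26 gene lists: ATF4 and CHOP targets, amino acid synthesis and transport, cytosolic aminoacyl-tRNA synthetases, ER chaperones, XBP1 targets, notochord lineage, H3K27 methylation machinery, HOX genes, hypoxia (HIF) targets, metallothioneins and zinc export, cholesterol synthesis, G1/S, G2/M, p53 targets, BCL2 family and death receptors, NRF2 targets, heat shock, NF-kB, interferon, immediate early, cytosolic ribosomal proteins, mitochondrially encoded transcripts, replication-dependent histones, cartilage and matrix, YAP and TEAD targets, and markers of other cell types. Lists with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Alternatives were a correlation estimated per list, and fry. Histones had 3 tested members in each experiment and the markers of other cell types 4 in the factorial, too few for a test. Member counts are given over all genes and, where these differ, adjusted over the list alone. The comparisons, tests, lists, named-gene rule and alternatives were chosen before the data were examined, except where stated. The named members and their directions are relative to the median of all genes, which library size alone shifted by 0.12 for KDOBA67 against DMSO and by 0.13 for the same comparison with ISRIB.

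Alternatives were DESeq2 1.42.0, relative log expression size factors, library size alone, no low-count filter, the libraries of the compared groups only, all 22 libraries in 1 fit, the replicate block, and leaving out each library in turn. A set of 7 further gene lists (lysosome, epidermal differentiation, transcripts with iron-responsive elements, JmjC histone demethylases, nuclear-encoded respiratory chain subunits, mitochondrial transcription and RNA stability, and mitochondrial ribosomal proteins) was chosen after the data were seen.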

Results

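UCH1 is an established chordoma cell line, and chordoma is a bone tumour of notochord lineage marked by the transcription factor brachyury, the product of TBXT. RNA-seq covered 22 libraries in 9 groups. In a factorial experiment, cells were exposed for 48 h to DMSO, to ISRIB (a compound that counters the integrated stress response), to KDOBA67 (an inhibitor of the KDM6 histone H3K27 demethylases), or to ISRIB plus KDOBA67, with 3 libraries each. In a time course, cells were exposed to KDOBA67 for 3, 6, 24 or 48 h and compared with DMSO at 0 h, with 2 libraries each (replicates 1 and 3). The questions were whether KDOBA67 lowers TBXT and raises stress and death genes, whether ISRIB alters that response, and in which order the changes come. Depth was 12038372 to 22046301 counts per library in the factorial and 6001519 to 19351439 in the time course. The first principal component held 87.5% of the variance in the factorial and the second 2.86%. The same components held 40.9% and 29.9% in the time course.

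In cells exposed to KDOBA67 for 48 h, TBXT fell from 1090 ± 21 to 355 ± 16.8 CPM (n = 3 per group; log2 fold change -1.62, SE 0.04, adjusted p = 1.2e-26, edgeR quasi-likelihood test). SHH, which encodes a ligand made by the notochord, fell from 67.3 ± 1.75 to 4.18 ± 0.617 CPM (-3.98). Genes of the integrated stress response rose. ATF3, a transcription factor of that response, went from 30.9 ± 0.903 to 150 ± 6.79 CPM (2.28, SE 0.06), and ASNS, which encodes asparagine synthetase, from 52.0 ± 2.38 to 193 ± 11.4 CPM (1.90, SE 0.05). The pro-apoptotic factor DDIT3 (CHOP) rose by 2.04, the glutathione-degrading enzyme CHAC1 by 2.41, the kinase-like protein TRIB3 by 1.14 and the factor ATF4 by 1.11. Of the targets of the inhibitor, KDM6B rose by 0.74 (SE 0.08, adjusted p = 9.2e-10) and KDM6A by 0.15 (SE 0.06, adjusted p = 0.042). The KDM6A call ended without KDOBA67 replicate 1 or 3 or DMSO replicate 1 or 2 (adjusted p = 0.12, 0.14, 0.12 and 0.13).

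The threshold was passed by 10147 of 13578 genes, 5192 higher and 4955 lower. Changes of at least 2-fold numbered 1626 higher and 1088 lower. The 10 largest rises were in SPINK1, a trypsin inhibitor (7.43; 0.298 to 52.2 CPM), LINC01164 (6.96), the epidermal protein gene FLG (6.66; 0.601 to 62.5 CPM), the YAP target ANKRD1 (6.46), IGFN1 (6.32), the activin subunit INHBA (6.24; 1.02 to 74.2 CPM), the growth factor PGF (6.17), the microfibril gene MFAP5 (5.77), SUGCT (5.49) and the stress cytokine GDF15 (5.42; 21.2 ± 1.82 to 915 ± 43.5 CPM). The 10 largest falls were in the imprinted gene MEST (-5.95; 30.8 to 0.483 CPM), TSPAN18 (-4.81), the polarity gene CRB1 (-4.81), NKAIN2 (-4.29), the ligand WNT8A (-4.23), the VEGF receptor KDR (-4.03), SHH, the potassium channel KCND2 (-3.95), TNFRSF11B, which encodes osteoprotegerin (-3.95; 612 to 39.5 CPM), and the homeobox gene SIX3 (-3.90).

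**Figure D1:**
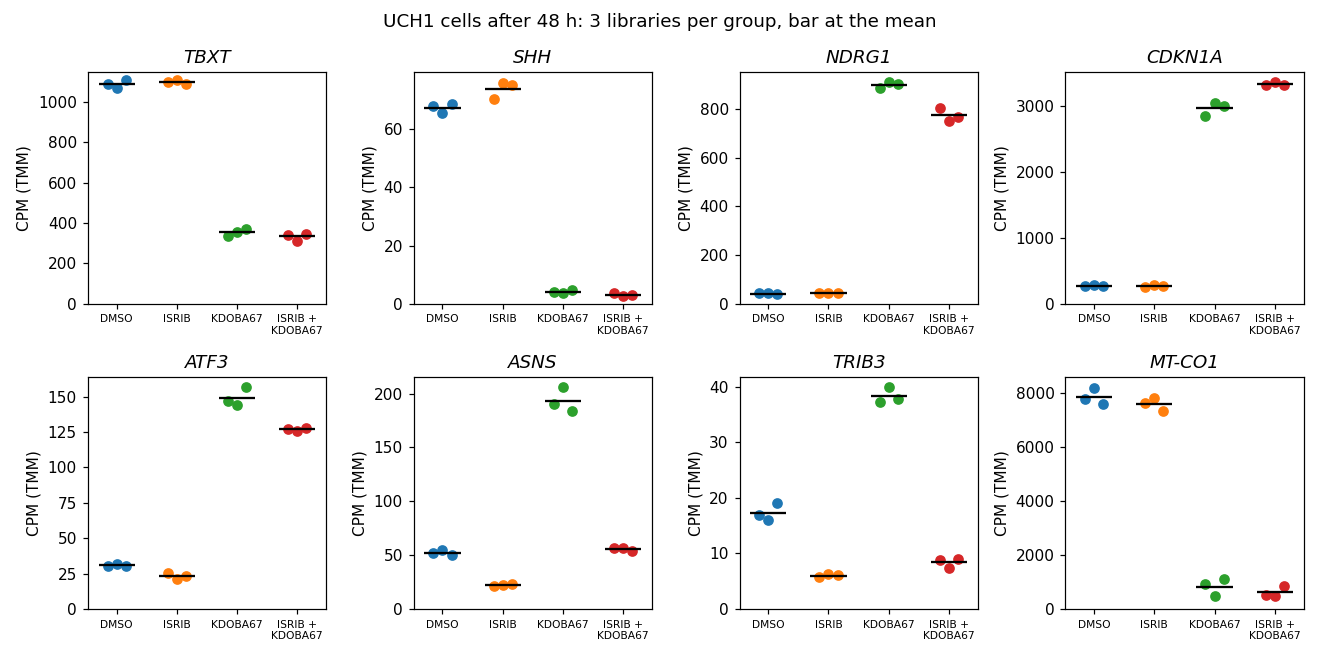
Levels of 8 genes in UCH1 cells after 48 h of DMSO, ISRIB, KDOBA67 or ISRIB plus KDOBA67. Each point is 1 library (n = 3 per group) and each bar a mean. ATF3, ASNS and TRIB3 are genes of the integrated stress response, NDRG1 is a HIF target and CDKN1A a p53 target.

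Stress, hypoxia and p53 groups rose with KDOBA67. Of 19 ATF4 and CHOP targets, 17 rose and 2 fell (median log2 change 1.85, camera adjusted p = 4.7e-07), among them GDF15, NUPR1 (2.77) and SESN2 (2.43). All 19 HIF targets rose (median 1.64, adjusted p = 1.1e-09), including NDRG1 (4.44; 41.5 to 899 CPM), the prolyl hydroxylase EGLN3 (3.48), ANGPTL4 (2.82) and the mitophagy receptor BNIP3L (1.93). All 16 p53 targets rose (median 1.85, adjusted p = 1.1e-09), including the cell-cycle inhibitor CDKN1A (3.44; 274 to 2960 CPM), TP53INP1 (3.27), BTG2 (2.80) and GADD45A (2.51). In the BCL2 and death receptor list 9 of 12 rose and 1 fell (median 0.81, adjusted p = 0.00068), with PMAIP1 (2.25), TNFRSF10A (2.02), TNFRSF10B (1.60) and BCL2L1 (1.31) higher. With a correlation estimated per list these 4 lists kept adjusted p = 0.025, 0.025, 0.0037 and 0.03 in that order. With the replicate block and an estimated correlation, HIF targets had adjusted p = 0.05 and the BCL2 list 0.053.

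Notochord and mitotic genes fell. Of 13 notochord genes 11 fell and 1, the BMP inhibitor NOG, rose (2.67), with a list median of -1.35 (camera adjusted p = 8.3e-05, and 0.031 with an estimated correlation, 0.05 with the block as well). KRT18 (-1.89) and the matrix linker HAPLN1 (-2.60) were among the lower genes of the notochord and cartilage lists. All 18 G2/M genes fell (median -1.37, adjusted p = 2.1e-09, and 0.025 with an estimated correlation), including KIF20A (-3.21), PLK1 (-2.93), CCNB1 (-1.84) and TOP2A (-1.73).

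A further 8 lists passed camera with the preset correlation, but not with an estimated correlation. They also passed fry (fry adjusted p at most 5.4e-05). Fry does not compare a list with the other genes, and most genes passed the threshold here, so it adds little. All 13 mitochondrially encoded transcripts fell (median -2.27, camera adjusted p = 0.00021, but adjusted p = 0.42 with an estimated correlation). MT-CO3, a cytochrome oxidase subunit, went from 4330 ± 153 to 353 ± 113 CPM (-3.61), with MT-CO1 (-3.24), MT-CO2 (-2.95) and MT-ATP8 (-2.53) also lower. Their share of all counts was 3.96 to 4.14% in DMSO and 0.634 to 1.29% with KDOBA67. Amino acid synthesis and transport genes had 14 higher and 2 lower of 18 (median 0.95, adjusted p = 0.00031, but adjusted p = 0.071 with an estimated correlation), with PSAT1 (1.40), SLC1A5 (1.09) and MTHFD2 (1.06) higher. Aminoacyl-tRNA synthetases had 14 higher and 6 lower of 20 (median 0.32, adjusted p = 0.027, but adjusted p = 0.36 with an estimated correlation), with GARS1 (1.46), SARS1 (1.08) and CARS1 (1.02) higher. All 5 metallothionein and zinc export genes rose (median 3.84, adjusted p = 0.00084, but adjusted p = 0.07 with an estimated correlation, 0.05 with the block as well). These include MT1X (4.23) and MT2A (3.84), whose reads can be shared with near-identical copies. NRF2 targets had 13 higher and 2 lower of 16 (median 0.66, adjusted p = 0.00031, but adjusted p = 0.11 with an estimated correlation), with the heme oxygenase HMOX1 at 4.84 (20.1 to 575 CPM) and AKR1C1 at 3.66.

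Immediate early genes had 12 higher and 1 lower of 14 (median 0.94, camera adjusted p = 0.00034, but adjusted p = 0.07 with an estimated correlation), with DUSP1 (1.42) and JUN (0.92) higher. NF-kB genes had 9 higher and 1 lower of 11 (median 0.76, adjusted p = 0.023, but adjusted p = 0.18 with an estimated correlation), with CXCL8 (2.02) higher and CXCL1 (-1.38) lower. G1/S genes had 2 higher and 14 lower of 19 (median -0.52, adjusted p = 0.00058, but adjusted p = 0.12 with an estimated correlation), with CCNE1 (-1.36) and MCM3 (-1.32) lower and PCNA (0.87) higher. Cartilage and matrix genes had 3 higher and 8 lower of 13 (median -0.56, adjusted p = 0.052, 0.039 with the replicate block, but adjusted p = 0.54 with an estimated correlation, 0.41 with the block as well), with COL9A1 (-3.12) and COL2A1 (-1.67) lower and VCAN (2.05) higher.

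**Figure D2:**
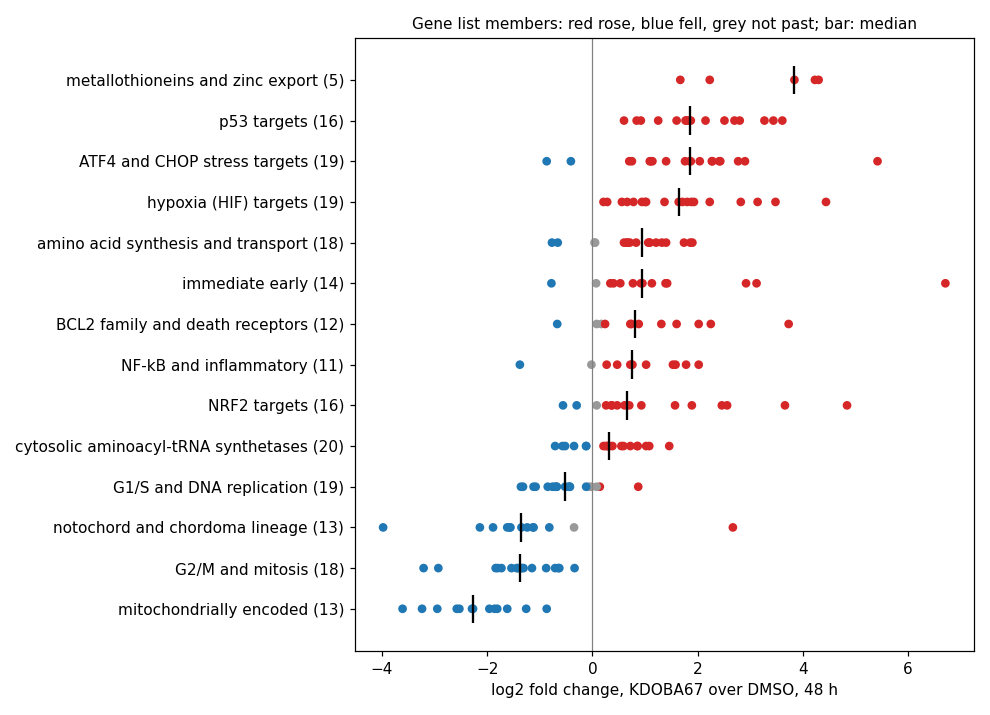
Log2 fold change with KDOBA67 of every tested member of the 14 gene lists that passed the camera test with the preset correlation. Red members rose, blue members fell and grey members did not pass the threshold. Numbers in brackets are tested members.

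The other lists did not pass the camera test or had too few members for it. H3K27 methylation genes had 5 higher and 6 lower of 12 (adjusted p = 0.56), with PHF19, a Polycomb accessory factor, lower (-2.21; 185 to 39.6 CPM), SUZ12 lower (-0.42) and EZH1 higher (1.00). HOX genes had 10 higher and 7 lower of 24 (0.56), with HOXB9 (2.34) higher and HOXA3 (-1.05) lower. ER chaperones had 7 higher and 3 lower of 14 (0.35), with HERPUD1 (1.21) higher and HSP90B1 (-0.60) lower, and XBP1 targets 6 and 5 of 12 (0.63), with DNAJB9 (0.87) higher and SEC24D (-1.10) lower. Cholesterol synthesis had 12 and 6 of 20 (0.15), with INSIG1 (1.04) higher, and interferon genes 8 and 6 of 16 (0.91), with ISG15 (1.52) higher. Heat shock genes had 1 and 8 of 12 (9 lower adjusted over the list alone; 0.092), with HSP90AA1 at -0.32. YAP and TEAD targets had 6 and 4 of 11 (0.46), with AMOTL1 (1.73) higher and CCN2 (-2.75) lower, and ribosomal proteins 7 and 4 of 20 (0.56). Of 3 tested histones, H1-2 (0.77) and H2BC21 (0.61) rose and H2BC4 (-0.63) fell. All 4 tested markers of other cell types rose, namely CD68 (1.56; 70.1 to 205 CPM) and, near the floor, LYZ, DES and RBFOX3. Adjusted over the list alone, the counts of the other 25 lists were equal to those over all genes.

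With ISRIB present throughout, KDOBA67 again lowered TBXT, from 1100 ± 10.1 to 334 ± 17.7 CPM (log2 fold change -1.73, adjusted p = 2e-27, edgeR quasi-likelihood test), and SHH, from 73.8 to 3.10 CPM (-4.58). ATF3 rose by 2.44, CHAC1 by 1.74, DDIT3 by 1.61, ASNS by 1.32, ATF4 by 0.70, TRIB3 by 0.49 (adjusted p = 0.00028) and KDM6B by 0.39 (adjusted p = 8.1e-05). KDM6A did not pass (0.03, adjusted p = 0.63). The threshold was passed by 10321 genes, 5279 higher and 5042 lower, and by 1493 and 1183 at 2-fold. The 5 largest rises were in SPINK1 (8.54), LINC01164 (7.08), FLG (6.71), MFAP5 (6.64) and ANKRD1 (6.46), and the largest falls in TSPAN18 (-6.08), MEST (-5.40), CRB1 (-4.72), SHH and NKAIN2 (-4.49). The responses without and with ISRIB correlated at r = 0.953 over all tested genes, with 4563 genes higher in both (2020 expected) and 4399 lower in both (1840 expected). Opposite directions were seen for 61 genes.

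With ISRIB present, 16 of 19 ATF4 and CHOP targets rose and 1 fell (17 and 1 adjusted over the list alone; median 1.61, camera adjusted p = 7.2e-06), GDF15 by 5.81. HIF targets had 18 of 19 higher (median 1.47, adjusted p = 3.4e-09), p53 targets 16 of 16 (median 1.90, adjusted p = 1.9e-09), with CDKN1A at 3.61 and BBC3 at 3.95, and the BCL2 list 10 of 12 (adjusted p = 0.00083), with 1 lower. Notochord genes had 11 of 13 lower and 1 higher (median -1.72, adjusted p = 7.7e-05), and all 18 G2/M genes fell (median -1.19, adjusted p = 4.2e-08). These 6 lists had adjusted p of 0.0036 for p53 and 0.032 for the others with an estimated correlation. With the replicate block as well, the ATF4, HIF, notochord and G2/M lists had adjusted p = 0.055 and the BCL2 list 0.059. All 13 mitochondrially encoded transcripts fell (median -2.57, adjusted p = 7.7e-05, but adjusted p = 0.42 with an estimated correlation), MT-CO3 by -3.97. All 5 metallothionein genes rose (median 4.05, adjusted p = 0.00083, but adjusted p = 0.066 with an estimated correlation), and 13 of 16 NRF2 targets with 2 lower (adjusted p = 0.00021, but adjusted p = 0.11 with an estimated correlation), HMOX1 by 5.21.

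Of the remaining lists with ISRIB present, immediate early genes had 12 higher and 1 lower (camera adjusted p = 0.00064, but adjusted p = 0.08 with an estimated correlation). NF-kB genes had 9 and 1 (0.015, but adjusted p = 0.17 with an estimated correlation), G1/S genes 3 and 13 (0.0086, but adjusted p = 0.25 with an estimated correlation) and cartilage genes 2 and 9 (median -0.80, 0.025, but adjusted p = 0.5 with an estimated correlation). Ribosomal proteins had 15 and 1 (median 0.24, 0.03, but adjusted p = 0.74 with an estimated correlation). Cholesterol synthesis had 13 and 3 (13 and 4 adjusted over the list alone; median 0.29, adjusted p = 0.038, 0.052 with the block, and adjusted p = 0.25 with an estimated correlation). No call was made for amino acid genes (12 and 6, adjusted p = 0.11), tRNA synthetases (8 and 6, 7 and 6 over the list alone, 0.68), ER chaperones (6 and 6, 0.68), XBP1 targets (5 and 4, 0.55), H3K27 genes (4 and 6, 0.68), HOX genes (9 and 8, 0.81), heat shock (4 and 5, 5 and 5 over the list alone, 1), interferon (9 and 6, 0.51) or YAP targets (6 and 5, 0.81). Of 3 histones 2 rose, and all 4 markers of other cell types rose.

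Adding ISRIB to KDOBA67 lowered genes of the integrated stress response and left TBXT without a call. TRIB3 fell from 38.3 to 8.43 CPM (log2 fold change -2.18), ASNS from 193 to 55.9 CPM (-1.79) and CHAC1 from 48.4 to 16 CPM (-1.60). DDIT3 fell from 119 to 69.2 CPM (-0.79), ATF4 from 236 to 145 CPM (-0.71) and ATF3 by -0.24 (adjusted p = 4.5e-04, edgeR quasi-likelihood test). TBXT (-0.09, adjusted p = 0.17), KDM6A (-0.07, adjusted p = 0.45) and KDM6B (-0.19, adjusted p = 0.088) did not pass. The threshold was passed by 2529 genes, 1300 higher and 1229 lower, with 7 and 82 at 2-fold. The 10 largest falls were in TRIB3, PAPPA2 (-2.15), the serine synthesis enzyme PHGDH (-1.97; 39.6 to 10.1 CPM), CBS (-1.89), ASNS, S100P (-1.63), CHAC1, PCK2 (-1.44), the folate enzyme ALDH1L2 (-1.42) and CSTA (-1.35). Under the same rule (mean CPM of at least 5, no overlap between libraries), which left out the 7 genes higher at 2-fold, the 10 largest rises were smaller. They were in IFIT1 (0.70), HAS3 (0.67), MPZL2 (0.67), DIO3 (0.59), NPTX2 (0.58), FABP4 (0.57), RASL11A (0.53), ID3 (0.52), HAPLN3 (0.50) and IFI30 (0.50). RASL11A did not pass without KDOBA67 replicate 3 (adjusted p = 0.078) or ISRIB plus KDOBA67 replicate 2 (adjusted p = 0.074).

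By group, 18 of 19 ATF4 and CHOP targets fell and 1 rose (median -0.71, camera adjusted p = 1.5e-19), NUPR1 by -0.91 and CEBPG by -0.83. Amino acid genes had 16 of 18 lower (median -0.79, adjusted p = 1.5e-23), PSAT1 by -1.07. tRNA synthetases had 13 of 20 lower and 1 higher (3 higher adjusted over the list alone; median -0.36, adjusted p = 4.2e-10), with WARS1 (-1.31) and AARS1 (-0.99). G2/M genes had 14 of 18 higher (15 over the list alone; median 0.21, adjusted p = 1.4e-09), with CCNB1 (0.48) and PLK1 (0.45), and cholesterol synthesis 12 of 20 (14 over the list alone; median 0.17, adjusted p = 1.9e-06), with INSIG1 (0.32). These 5 lists held with an estimated correlation (adjusted p = 0.0015 for the ATF4 and amino acid lists and 0.023 for the others), and with the block as well tRNA synthetases and cholesterol synthesis had adjusted p = 0.051. G1/S genes had 8 higher (median 0.12, adjusted p = 0.00027, but adjusted p = 0.14 with an estimated correlation), with CCNE1 at 0.34, and heat shock genes 9 (11 over the list alone; median 0.17, adjusted p = 9.6e-06, but adjusted p = 0.13 with an estimated correlation), with HSPE1 at 0.37. Ribosomal proteins had 10 higher (13 over the list alone; 0.13, adjusted p = 0.00017, but adjusted p = 0.72 with an estimated correlation) and interferon genes 7 (8 over the list alone; 0.31, adjusted p = 0.0073, but adjusted p = 0.56 with an estimated correlation), with IFI44 at 0.47. Mitochondrially encoded transcripts had 0 of 13 past the edgeR threshold (median -0.40, adjusted p = 0.035, but adjusted p = 0.83 with an estimated correlation).

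The other lists were not called for ISRIB added to KDOBA67. Higher and lower members were 6 and 4 for ER chaperones (7 and 4 over the list alone, camera adjusted p = 0.46), 3 and 1 for XBP1 targets (0.62), 1 and 2 for notochord genes (0.78), 2 and 0 for H3K27 genes (0.78), 1 and 2 for HOX genes (0.9) and 2 and 3 for HIF targets (4 and 4 over the list alone, 0.62), with VEGFA at -0.36. They were 1 and 1 for metallothioneins (0.96), 4 and 4 for p53 targets (0.78), 2 and 3 for the BCL2 list (0.69), with PMAIP1 at -0.33, 3 and 4 for NRF2 targets (0.78), 1 and 1 for NF-kB (0.62), 1 and 0 for immediate early genes (0.62), 2 and 1 for cartilage (0.41) and 3 and 3 for YAP targets (0.41). All 3 histones rose, H1-2 by 0.34, and of the 4 markers of other cell types 0 passed.

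**Figure D3:**
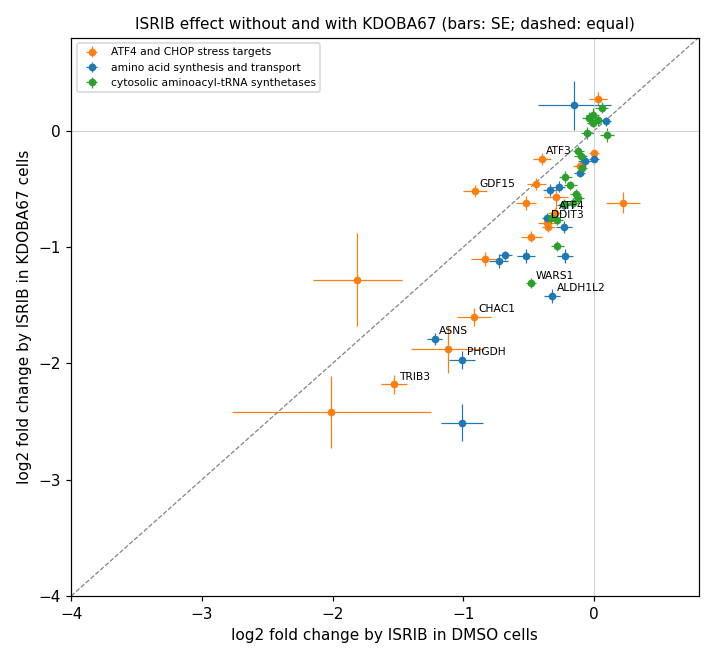
Log2 fold change by ISRIB in DMSO cells against that in KDOBA67 cells for members of 3 lists, with standard errors. On the dashed line the effects are equal.

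ISRIB without KDOBA67 lowered the same stress genes. TRIB3 fell from 17.3 to 6.01 CPM (log2 fold change -1.53), ASNS from 52.0 to 22.2 CPM (-1.22), CHAC1 by -0.92, ATF3 by -0.40, DDIT3 by -0.36 and ATF4 by -0.30. TBXT (0.02, adjusted p = 0.94, edgeR quasi-likelihood test), KDM6A (0.04, adjusted p = 0.92) and KDM6B (0.17, adjusted p = 0.6) did not pass. The threshold was passed by 81 genes, 23 higher and 58 lower, with 0 and 13 at 2-fold, and by 125 with the block (57 higher and 68 lower). Without a single library the count was 49 (ISRIB replicate 3), 52 (DMSO replicate 1) or 296 (DMSO replicate 3; 200 higher and 96 lower). Other large falls were in PAPPA2 (-1.16), CBS (-1.08), PHGDH (-1.01), GDF15 (-0.91), DDIT4 (-0.83), the cystine transporter SLC7A11 (-0.73) and PCK2 (-0.69). ATF4 did not pass without DMSO replicate 1 (adjusted p = 0.053) and DDIT3 without ISRIB replicate 3 (adjusted p = 0.05). The 10 largest rises were in NPTX1 (0.48), CCDC142 (0.46), ANGPTL4 (0.45), COL27A1 (0.39), PPFIA4 (0.38), JAG1 (0.31), CSF1 (0.31), ADAMTS15 (0.28), NDUFA4L2 (0.27) and RAPGEF3 (0.26), and of these only ANGPTL4 passed whichever single library was left out. Of the genes lower with ISRIB alone, 53 were also lower when ISRIB was added to KDOBA67 (5.25 expected). Of the genes higher with ISRIB alone, 2 were also higher (2.2 expected), and 4 genes called in both went in opposite directions. Over all tested genes the ISRIB effects without and with KDOBA67 correlated at r = 0.124 (Spearman 0.0168). With ISRIB alone 81 of 13578 genes were called, so spread between libraries can lower this value, which does not by itself show different effects.

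ATF4 and CHOP targets had 12 of 19 lower with ISRIB alone (15 adjusted over the list alone; median -0.44, camera adjusted p = 2.5e-26), amino acid genes 11 of 18 (14 lower and 1 higher over the list alone; -0.30, 2.5e-26) and tRNA synthetases 5 of 20 (12 over the list alone; -0.12, 9.2e-12). These held with an estimated correlation (adjusted p = 0.0008, 0.0008 and 0.025), and with the block as well tRNA synthetases had adjusted p = 0.051. HIF targets had 2 higher (adjusted p = 5.5e-05, but adjusted p = 0.14 with an estimated correlation), cholesterol synthesis 1 (3 over the list alone; 0.0036, but adjusted p = 0.17 with an estimated correlation) and YAP targets 1 (3 over the list alone; 0.0036, but adjusted p = 0.27 with an estimated correlation). NRF2 targets had 1 lower (0.0015, but adjusted p = 0.24 with an estimated correlation). ER chaperones (adjusted p = 0.0087), metallothioneins (0.047), immediate early genes (0.03) and cartilage (0.041) also passed. With an estimated correlation these had adjusted p = 0.27, 0.27, 0.27 and 0.61. The other lists were not called.

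The interaction asked where the KDOBA67 response differed with ISRIB. The rise of CHAC1 was smaller by 0.68 with ISRIB (log2 difference -0.68, adjusted p = 0.0062, edgeR quasi-likelihood test), that of TRIB3 by 0.65 (adjusted p = 0.0032), ASNS by 0.57 (adjusted p = 2.5e-05), DDIT3 by 0.43 (adjusted p = 0.0018) and ATF4 by 0.41 (adjusted p = 0.00041). ATF3 (0.16, adjusted p = 0.24), TBXT (-0.11, adjusted p = 0.3), KDM6B (-0.36, adjusted p = 0.062) and KDM6A (-0.11, adjusted p = 0.51) did not pass. The threshold was passed by 940 genes, 431 with a higher and 509 with a lower response (498 and 458 by library size alone), 3 and 23 at 2-fold. Without a single library the count was 421 (ISRIB replicate 3), 452 (DMSO replicate 1), 493 (DMSO replicate 2), 613 (KDOBA67 replicate 1), 621 (ISRIB replicate 2 and KDOBA67 replicate 3) or 1895 (DMSO replicate 3; 959 higher and 936 lower). Among the largest in each direction with a mean CPM of at least 5 were NPTX1 (-1.26), the matrix gene TNC (-1.13), ALDH1L2 (-1.10), S100P (-1.03) and PAPPA2 (-0.98), and IFIT1 (0.83; adjusted p = 0.039, 0.059 with the block), DLL3 (0.72), MPZL2 (0.62) and TST (0.61). DLL3 did not pass without KDOBA67 replicate 3, ISRIB replicate 3, ISRIB plus KDOBA67 replicate 1 or DMSO replicate 1 or 2 (adjusted p = 0.07, 0.068, 0.069, 0.068 and 0.053). IFIT1 did not pass without ISRIB replicate 2 or 3, KDOBA67 replicate 1 or 3, ISRIB plus KDOBA67 replicate 3 or DMSO replicate 1 or 2 (adjusted p = 0.061 to 0.12).

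Amino acid genes had a lower response in 13 of 18 (16 adjusted over the list alone; median -0.39, camera adjusted p = 1.8e-15, 0.0098 with an estimated correlation and 0.064 with the block as well), with PHGDH (-0.96), SLC7A1 (-0.86) and SLC1A4 (-0.60). ATF4 and CHOP targets had 8 lower and 1 higher (9 and 2 over the list alone; adjusted p = 4.1e-05, but adjusted p = 0.084 with an estimated correlation), with STC2 (-0.84) and CEBPG (-0.48), and tRNA synthetases 10 lower (11 over the list alone; 7.8e-07, but adjusted p = 0.084 with an estimated correlation), with WARS1 (-0.83). G2/M genes had 8 with a higher response (13 over the list alone; 9.5e-08, but adjusted p = 0.063 with an estimated correlation), with PLK1 (0.48), CCNB1 (0.47) and TTK (0.35). Heat shock had 4 higher (7 over the list alone; 7e-05, but adjusted p = 0.21 with an estimated correlation), ribosomal proteins 2 (8 over the list alone; 5e-05, but adjusted p = 0.49 with an estimated correlation) and G1/S genes 2 (4 over the list alone; 0.0023, but adjusted p = 0.24 with an estimated correlation). Cholesterol synthesis had 2 higher (4 over the list alone; 0.0088, but adjusted p = 0.21 with an estimated correlation), interferon genes 3 (0.012, but adjusted p = 0.49 with an estimated correlation) and YAP targets 2 lower (4 over the list alone; 0.016, but adjusted p = 0.43 with an estimated correlation). Cartilage had adjusted p = 0.063, and 0.022 with the block. The other lists were not called.

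In the time course, ADM, a HIF target that encodes adrenomedullin, rose at every time. It went from 7.90 CPM at 0 h to 30.6 CPM at 3 h (log2 fold change 1.95, SE 0.15, adjusted p = 0.023, edgeR quasi-likelihood test, n = 2 per group). Its changes at 6, 24 and 48 h were 1.78 (adjusted p = 0.046), 1.77 (adjusted p = 0.046) and 1.68 (adjusted p = 0.034). At 48 h COQ8A, a gene of coenzyme Q synthesis, rose from 33.6 to 94.9 CPM (1.50, SE 0.13, adjusted p = 0.034). No other gene passed by edgeR without the block. Leaving out any library of the groups compared ended the ADM call at 3, 6 and 24 h (highest adjusted p = 0.56, 1 and 0.78), and at 48 h only the fit without replicate 3 at 48 h kept ADM and COQ8A (adjusted p = 0.49 without 0 h replicate 1, 0.32 without 0 h replicate 3 and 0.24 without 48 h replicate 1). An unadjusted p under 0.05 was reached by 75, 414, 1032 and 1916 genes at 3, 6, 24 and 48 h. With the replicate block, 3, 52, 166 and 1266 genes passed, and by DESeq2 without the block 6, 43, 79 and 453. DMSO was sampled at 0 h only, so time in culture and KDOBA67 changed together.

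TBXT did not pass at any time. Its log2 changes were -0.15, -0.35, -0.68 and -0.79 at 3, 6, 24 and 48 h (adjusted p = 1, 1, 0.73 and 0.44, and 0.17 at 48 h with the block). In replicate 1 TBXT was at 1040, 887, 636, 440 and 310 CPM from 0 to 48 h, and in replicate 3 at 850, 822, 845, 742 and 786 CPM. At 48 h, KDM6B had 0.89 (adjusted p = 0.22, but 0.043 with the block at 0.86). CHAC1 (2.12, adjusted p = 0.47), DDIT3 (2.04, adjusted p = 0.37), ATF3 (1.99, adjusted p = 0.32), ASNS (1.63, adjusted p = 0.53), TRIB3 (1.06, adjusted p = 0.71), ATF4 (0.95, adjusted p = 0.42) and KDM6A (0.14, adjusted p = 0.63) did not pass. ATF4 went from 81.1 to 258 CPM between 0 and 48 h in replicate 1 and from 103 to 95.9 CPM in replicate 3. ASNS went from 19.7 to 207 CPM and from 57.4 to 31.6 CPM in the same replicates.

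**Figure D4:**
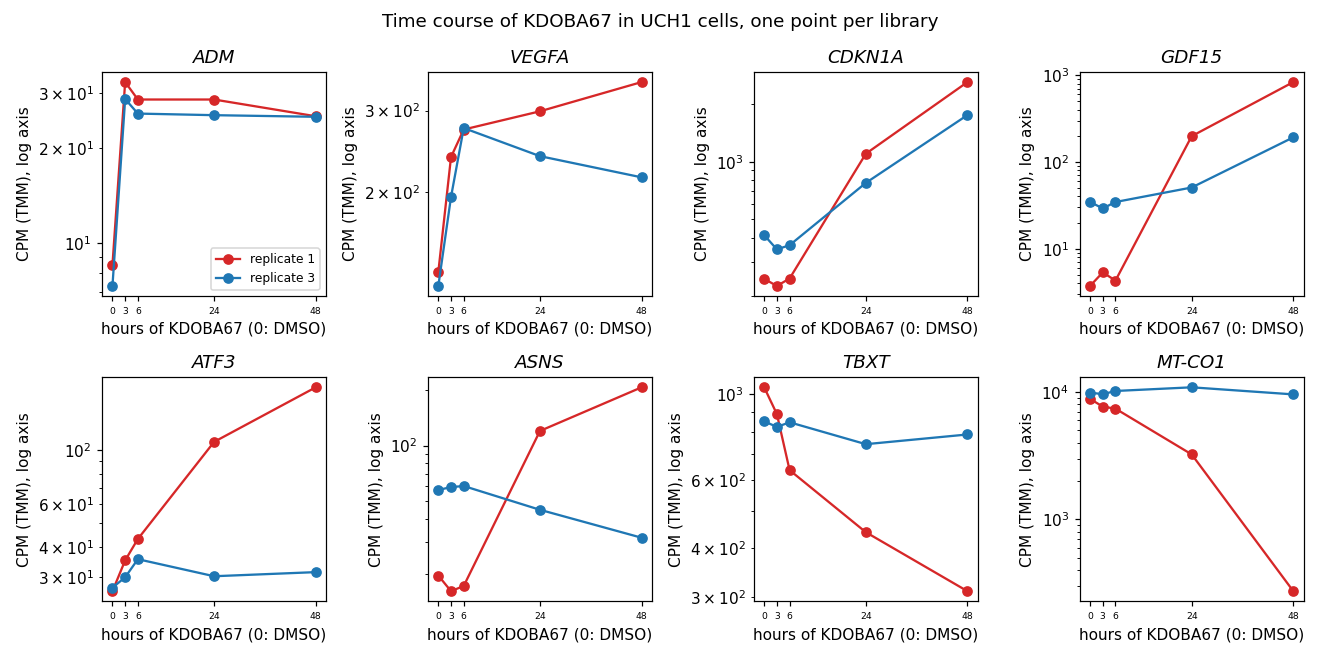
Levels of 8 genes in UCH1 cells at 0 h (DMSO) and after 3, 6, 24 and 48 h of KDOBA67, 1 point per library and 1 line per replicate, on a log axis.

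With the replicate block, the called genes at 3 h were ADM, the lipid droplet gene HILPDA (1.78, adjusted p = 0.034) and the repressor BHLHE40 (1.35, adjusted p = 0.034). At 6 h, 50 genes were higher and 2 lower. The largest were FAM117B (2.46), LANCL3 (2.28), HILPDA (2.14), PCDH10 (1.88) and ADM, and the lower genes DLL1 (-1.91) and C1orf115 (-1.62). The HIF targets EGLN1 (1.29), BNIP3L (1.17) and VEGFA (1.08) also rose. At 24 h, 131 were higher and 35 lower, among the largest ABCG8 (3.27), CA9 (2.32), LOX (2.04) and NDRG1 (1.91), and PLB1 (-1.91), CXXC4 (-1.75), C1orf115 (-1.41) and BEX1 (-1.30). Without a single library the blocked counts lay at 0 to 3, 0 to 10 and 0 to 31 at 3, 6 and 24 h.

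At 48 h with the block, 726 genes were higher and 540 lower, 255 and 168 at 2-fold. The 10 largest rises were in LINC01164 (4.97), FLG (4.15), NECTIN4 (4.02), LRATD1 (3.20), GREB1 (3.19), SUGCT (3.19), ABCG8 (3.19), MT1X (3.09), the pro-apoptotic BBC3 (3.05) and COL17A1 (2.90). The 10 largest falls were in MEST (-3.00), CHRM1 (-2.68), CYP24A1 (-2.48), ADAMTS16 (-2.35), KDR (-2.28), TNFRSF11B (-2.20), CDH1 (-2.10), SHH (-1.99), ZNF467 (-1.92) and LOXL4 (-1.87). CDKN1A (2.76, blocked adjusted p = 0.014), NDRG1 (2.59) and FAS (1.25) rose as well. Without a single library the blocked count was 11 (0 h replicate 1), 273 (0 h replicate 3), 457 (48 h replicate 1) or 3501 (48 h replicate 3).

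Gene lists in the time course passed only camera with the preset correlation, and with an estimated correlation or by fry no list passed at any time. Counts of members over all genes were 0 unless given. HIF targets had medians of 0.61, 1.03, 1.05 and 0.97 at 3, 6, 24 and 48 h (camera adjusted p = 1e-19, 1e-19, 2.2e-13 and 7.2e-09, but adjusted p = 0.95, 0.44, 0.44 and 0.62 with an estimated correlation), with 1 of 19 members, ADM, higher each time. Adjusted over the list alone, 6, 8 and 9 were higher at 6, 24 and 48 h, and with the block 1, 5, 9 and 10 were higher from 3 to 48 h. The p53 targets had a median of 0.95 at 24 h (1.1e-09, but adjusted p = 0.44 with an estimated correlation; 7 higher over the list alone) and 1.67 at 48 h (1.7e-14, but adjusted p = 0.62 with an estimated correlation; 16 over the list alone and 12 with the block). Their medians in replicates 1 and 3 were 1.54 and 0.54 at 24 h, and 2.38 and 1.13 at 48 h. Immediate early genes had 0.25, 0.69 and 0.59 at 3, 6 and 24 h (9.3e-05, 5.9e-05 and 0.0068, but adjusted p = 0.99, 0.66 and 0.58 with an estimated correlation). ATF4 and CHOP targets had 1.11 at 24 h (0.00011, but adjusted p = 0.58 with an estimated correlation; 1 over the list alone) and 1.37 at 48 h (0.0024, but adjusted p = 0.77 with an estimated correlation). Replicate 1 alone carried their change, with 1.88 at 24 h and 2.78 at 48 h against 0.01 and -0.10 in replicate 3, and the 48 h median on the log2 CPM scale of the test was 0.80.

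Amino acid genes passed at 24 h (median 0.71, camera adjusted p = 0.0024, but adjusted p = 0.58 with an estimated correlation), with medians of 1.23 in replicate 1 and 0.01 in replicate 3. The BCL2 list passed at 24 and 48 h (0.45 and 0.56; 0.0049 and 0.0012, but adjusted p = 0.58 and 0.62 with an estimated correlation; 3 and 4 higher over the list alone), with medians of 0.72 and 0.80 in replicate 1 and 0.13 and 0.25 in replicate 3. Notochord genes passed at 24 and 48 h (-0.59 and -0.82; 0.013 and 0.00023, but adjusted p = 0.58 and 0.62 with an estimated correlation; 5 lower and 1 higher over the list alone at 48 h), with -0.84 and -1.68 in replicate 1 and -0.24 and -0.32 in replicate 3. At 24 h ribosomal proteins (-0.26; 0.00011, but adjusted p = 0.58 with an estimated correlation), HOX genes (-0.26; 0.029, but adjusted p = 0.44 with an estimated correlation) and interferon genes (-0.20; 0.016, but adjusted p = 0.44 with an estimated correlation; 1 lower over the list alone) passed, with medians in replicates 1 and 3 of -0.42 and -0.07, -0.22 and -0.24, and -0.28 and -0.11. At 48 h ER chaperones (0.041), G1/S genes (-0.63; 3.1e-05), mitochondrially encoded transcripts (-0.88; 0.00017) and cartilage (-0.70; 0.037) passed, with adjusted p = 0.66, 0.62, 0.66 and 0.66 with an estimated correlation. Medians in replicates 1 and 3 were 0.47 and 0.04 for ER chaperones, -0.96 and -0.23 for G1/S genes and -1.12 and -0.26 for cartilage. The mitochondrial value pools medians of -4.05 in replicate 1 and 0.03 in replicate 3, and on the log2 CPM scale of the test it was -2.02. The block added calls for metallothioneins (0.0065), NF-kB (0.046) and ribosomal proteins (0.023) at 3 h. It added XBP1 targets (0.046), metallothioneins (0.0023), NF-kB (0.0023) and YAP targets (0.046) at 6 h, ER chaperones (0.033) at 24 h, and G2/M (0.022) and immediate early genes (0.037) at 48 h. The ribosomal and G2/M lists were lower and the others higher. Medians in replicates 1 and 3 were -0.05 and -0.72 for G2/M at 48 h, after 0.59 and -0.38 at 24 h, and 0.69 and 0.26 for immediate early genes at 48 h. With the block and an estimated correlation the lowest adjusted p was 0.18.

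Between successive times of KDOBA67, edgeR called 0 genes from 3 to 6 h (119 at an unadjusted p under 0.05, 0 by DESeq2), 0 from 6 to 24 h (590 unadjusted, 8 by DESeq2) and 0 from 24 to 48 h (523 unadjusted, 10 by DESeq2). With the block, the histone gene H2AC6 rose (1.35, adjusted p = 0.025) and the matrix gene EPYC fell (-1.04, adjusted p = 0.027) from 24 to 48 h.

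The 48 h responses to KDOBA67 in the factorial and in the time course correlated at r = 0.804 (Spearman 0.762, 13380 genes), with a slope of 0.484. Among genes called in both with the time course blocked, 714 were higher in both (274 expected), 521 lower in both (198 expected) and 12 opposite. The replicates of the time course stood apart. Over 2551 genes called at 2-fold in the factorial, the slope of the response on the factorial was 0.041, 0.11, 0.36 and 0.62 at 3, 6, 24 and 48 h in replicate 1, and 0.034, 0.07, 0.21 and 0.26 in replicate 3. List medians at 48 h in replicates 1 and 3 were 2.78 and -0.10 for ATF4 and CHOP targets, -4.05 and 0.03 for mitochondrially encoded transcripts, -1.68 and -0.32 for notochord genes, 2.38 and 1.13 for p53 targets and 0.78 and 1.29 for HIF targets. Without the 48 h replicate 1 library the correlation between the experiments was 0.445, and without replicate 3 at 48 h 0.841.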

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

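The tests of explanations and the test of a difference between the experiments were chosen after the results were seen, while the interaction, the fixed gene lists and the counts over other splits of the libraries were planned. The interaction test gave 940 genes whose KDOBA67 response at 48 h differed with and without ISRIB, which drew attention as a difference between groups under the same contrast. Of the 200 ways to divide the libraries by ISRIB within each KDOBA67 arm, 40 were drawn, the real one included, and 1, the real one, gave as many genes. The highest of the others gave 13. The other splits mix libraries with and without ISRIB, so the ISRIB effect itself adds to their spread, and they cannot say whether chance is excluded for the interaction. For comparisons of 3 against 3 libraries, the 10 possible divisions are too few for a share under 0.05, and in each 1 division, the real one, gave as many genes. The real and highest other counts were 10147 and 0 for KDOBA67, 10321 and 0 for KDOBA67 with ISRIB, 2529 and 15 for ISRIB added to KDOBA67, and 81 and 0 for ISRIB alone. The other divisions here also mix libraries of both groups, so the treatment effect adds to their spread. Their low counts therefore say nothing about chance.

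A test of the difference between the experiments gave 513 genes, of 14082 tested, whose 48 h response differed between the factorial and the time course, 255 with a higher and 258 with a lower log2 change in the factorial. With the replicate block the count was 2822. Both counts come from a fit of all 22 libraries, which pools the spread of the factorial (median coefficient of variation 0.04) with that of the time course (0.212). The spread of the time-course side can therefore be understated, and the counts can be too high. Without a single library it lay between 130 (0 h replicate 1) and 2595 (48 h replicate 1), with 144 without 48 h replicate 3. The control was at 48 h in the factorial and at 0 h in the time course, so the count holds both a difference between experiments and one between controls.

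In the time course, the replicates answered with different gene groups at 48 h: ATF4 and CHOP targets had a median log2 change of 2.78 in replicate 1 and -0.10 in replicate 3, while HIF targets had 0.78 and 1.29. The tables argue against a shallower replicate 3 library, whose total count was 1.43 times that of replicate 1. Its HIF targets had a median change of 1.29, which argues against untreated cells at their 0 h level under a wrong label. Untreated cells kept for 48 h cannot be told apart by this value, because no DMSO library of the time course was taken at 48 h. A mixture of treated cells with untreated cells at their 0 h level would give both lists the same share of the replicate 1 change. Over members changed 2-fold in replicate 1, the median share was higher by 0.64 for HIF targets (0.39 to 3.7, 8 of 19 members) than for ATF4 and CHOP targets (-0.32 to 0.062, 15 of 19), lists picked because they differed. A mixture with untreated cells that changed over the 48 h stays open, because such cells were not sampled. A replicate 3 control already at the treated level is argued against by a median share of 0.3 of the replicate 1 rise present at 0 h. The replicates already stood apart at 0 h, at 2.54 and 35.7 on the first principal component and at 36.4 and -12.3 on the second (replicates 1 and 3). The labels carry replicate and donor numbers but do not say what sets these replicates apart, so no biological explanation was tested. A difference in dose or culture between the replicates stays open.

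Mitochondrially encoded transcripts fell with KDOBA67 in the factorial by a median of -2.27. The scaling between libraries is argued against as the cause, because on the log2 CPM scale the median was -2.34 with the TMM factors and -2.23 by library size alone. A fall of all respiratory chain transcripts to a like extent is argued against by the nuclear-encoded subunits (median -0.2, and -0.09 by library size alone). Of these, 13 of 25 did fall and 2 rose, so a smaller fall of the group is not excluded. Lower transcripts of a gene for mitochondrial transcription or RNA stability stay open, since 7 rose and 3 fell of 12 (median 0.17, lowest -0.36). Adding ISRIB to KDOBA67 lowered ATF4 and CHOP targets (median -0.71) and amino acid genes (median -0.79). The mitochondrially encoded transcripts did not recover along with this (median change -0.4, with 0 of 13 past the edgeR threshold). The integrated stress response as a whole stays open, because 16 of 19 ATF4 and CHOP targets still rose with KDOBA67 when ISRIB was present. Loss of mitochondrial DNA or faster RNA decay may also underlie the fall.

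HIF targets rose with KDOBA67. Time in culture is argued against for 48 h, because against DMSO libraries of the same 48 h the median was 1.64 in the factorial. At 3 h the median was 0.61, and time or handling cannot be told apart from KDOBA67 there because no DMSO library was sampled at 3 h. HIF prolyl hydroxylases use the same cofactors as KDM6 enzymes, so their inhibition by KDOBA67 may raise HIF targets, which these transcript data did not test.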

How the results depend on the processing

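The counts for KDOBA67 in the factorial stayed within 1.5 times of 10147 and 10321 under every alternative run, at 9728 to 10008 and 9875 to 10076 without a single library and at 7902 and 7934 with all 22 libraries. Alternatives of the blocked time course and the blocked values of the agreement and of the difference between experiments were chosen after seeing the data. Except where given, the cause was not tested.

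ISRIB alone gave 123 genes with no filter, 125 with the replicate block, 0 with all 22 libraries and 49 to 296 without a single library. With all 22 libraries, ISRIB added to KDOBA67 gave 1 and the interaction 1. That fit pools the larger spread of the time course (median coefficient of variation 0.212 against 0.04). The interaction gave 421 to 1895 without a single library.

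In the time course, DESeq2 called 6, 43, 79 and 453 genes at 3, 6, 24 and 48 h, 8 from 6 to 24 h and 10 from 24 to 48 h. The replicate block gave 3, 52, 166 and 1266, and 2 from 24 to 48 h. The libraries of the compared groups alone gave 0 at each time, with fewer libraries to estimate the spread. All 22 libraries gave 9, 151, 754 and 2352, and 137 and 182 for the later steps, with the smaller spread of the factorial pooled in. At 48 h, no filter gave 27, library size alone 1, and leaving out 1 library 0 to 167 (167 without replicate 3 at 48 h). Leaving out 1 library gave 0 at 3, 6 and 24 h and for each step. The lone library of a group was then assumed to vary like the other groups. With all of replicate 3 left out, no residual degrees of freedom remain.

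With the block, DESeq2 gave 25, 205 and 523 at 3, 6 and 24 h and no filter 101 at 6 h. Leaving out 1 library from the blocked fit gave 0 to 3, 0 to 10, 0 to 31 and 11 to 3501. The difference between experiments gave 2822 with the block and 130 to 2595 without a single library. The agreement of the experiments was 0.445 to 0.841 without a single library, and 0.639 without 0 h replicate 3.

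Of 120 list tests in the factorial 60 passed, and 21 did with an estimated correlation (63 by fry, 61 with the block, 61 by library size alone). Of 100 in the time course 23 passed, 0 with an estimated correlation, 0 by fry and 33 with the block. In the factorial, the block changed no other call of a named gene or list than those given. By library size alone, more genes were higher with KDOBA67 (6255 higher, 4034 lower) and with KDOBA67 in the presence of ISRIB (6396 higher, 3965 lower) and fewer with ISRIB alone (13 higher, 60 lower), the interaction had 498 higher and 458 lower, and the median of the H3K27 list moved from -0.12 to 0. Of 3834 values under the alternatives for 186 named genes (294 pairs of gene and comparison), 3520 kept their side of the threshold, 188 lost the call, 126 gained one, and 0 that were called in either fit changed direction. Depth limits the 6 h replicate 3 library most, where 3 counts equal 0.5 CPM.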

Other observations

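The tests of explanations and of 7 further gene lists were chosen after the results were seen, on planned comparisons of the factorial and, for the lists, on 48 h of the time course. At 48 h of the time course the lysosome (camera adjusted p = 0.001, higher), JmjC (0.0069, higher) and mitochondrial ribosomal lists (0.027, lower) passed. With an estimated correlation they had adjusted p = 0.41, 0.29 and 0.29, and no single member passed over all genes. CD68, a lysosomal membrane gene also used as a macrophage marker, rose with KDOBA67 in the factorial by a log2 change of 1.56. If CD68 follows the lysosome, other lysosomal genes should rise too, and 20 of 20 did (median 0.73, camera adjusted p = 1.2e-07, but adjusted p = 0.27 with an estimated correlation), including NEU1 (1.55), GLA (1.32), CTSA (0.90) and LAMP1 (0.70). Macrophages also hold many lysosomal transcripts, but all libraries came from 1 established chordoma cell line. In the same list of markers LYZ, another blood cell marker, lay near the floor, while CD68 did not. These points argue against macrophages as the source, and what raised CD68 in the UCH1 cells was not tested.

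FLG was among the largest rises with KDOBA67. Of 9 tested genes of epidermal differentiation 6 rose and 3 fell (camera adjusted p = 0.18), with CSTA (5.39), SERPINB7 (5.11) and IVL (4.57) higher and DSC2 (-1.84) and TGM1 (-1.54) lower, so a rise of the group may or may not accompany FLG.

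The transferrin receptor TFRC rose from 495 to 1290 CPM (1.38). If iron loss stabilised transcripts through iron-responsive elements in their 3' end, all such transcripts should rise. Of 4 tested, 2 rose, TFRC and SLC11A2 (0.14, not past the threshold without KDOBA67 replicate 3, adjusted p = 0.077, or DMSO replicate 2, adjusted p = 0.11), while CDC42BPA fell (-0.60) and CDC14A did not pass (0.40, adjusted p = 0.07). The counts are per gene, so transcripts of a gene with and without the element cannot be told apart. With members this few and in both directions, the explanation stays open. Over all 7 tested transcripts with such elements at either end, 4 rose and 2 fell (camera adjusted p = 0.18), a wider set that does not test the 3' end alone.

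Other JmjC histone demethylases had 10 higher and 3 lower of 14 (camera adjusted p = 0.056), with KDM7A (1.76), KDM3A (1.71) and KDM4B (1.23) higher and PHF8 (-0.44) lower. KDM3A also belongs to the HIF list, so its rise cannot be counted for a JmjC group apart from HIF targets. With ISRIB present the list had 9 higher and 3 lower (camera adjusted p = 0.14). At 48 h of the time course, where the list passed only with the preset correlation, 4 members were higher over the list alone. Whether the group may rise with KDM6B was left open by these tests.

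Among mitochondrial lists, nuclear-encoded respiratory chain subunits had 2 higher and 13 lower of 25 with KDOBA67 (camera adjusted p = 0.022, but adjusted p = 0.41 with an estimated correlation), with ATP5F1A at -0.74 and NDUFS3 at -0.53. When ISRIB was added to KDOBA67, 18 rose and 0 fell by edgeR (21 and 0 over the list alone; median 0.19, adjusted p = 3.9e-10, but adjusted p = 0.2 with an estimated correlation). Mitochondrial ribosomal proteins had 3 higher and 11 lower of 15 with KDOBA67 (adjusted p = 0.18). Mitochondrial transcription and RNA stability genes had 7 higher and 3 lower of 12 (adjusted p = 0.18), with TWNK (1.00) and LRPPRC (0.34) higher.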
